A study of Mus musculus with 6 samples.

How the data were processed

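RNA was sequenced from mouse lung endothelial cells isolated by fluorescence-activated cell sorting, in 3 libraries labelled wild type (WT) and 3 labelled knockout (KO) for the DNA methyltransferase gene Dnmt3a. Per the labels' protocols, RNA was extracted with a kit for small cell numbers, amplified to cDNA with a SMARTer ultra-low-input kit and sequenced as paired-end reads on an Illumina HiSeq. The gate of the sort, the allele, the age of the mice and whether all libraries came from separate animals are not given in the sources used here. Reads from a gene and from an antisense partner are not told apart here, because no source used here states that strand was kept.

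The authors deposited 2 gene tables with the same Ensembl identifiers. The first holds estimated counts per gene as deposited by the authors, in whole numbers and without normalization. The second holds TPM values that the authors computed, whose columns sum to 875864 to 885609; why they sum to less than the unit implies is not given in the sources used here. The submitters' processing notes name kallisto, with no version, and the genome build mm10. The annotation and the step that summed transcripts to genes are not given in the sources used here. Symbols and coordinates were taken from GENCODE M21 on the same assembly: 24298 of 24520 identifiers had a symbol and 221 were not in that annotation. No row was a summary row, and identifiers without a symbol took 0.030% to 0.040% of each library's counts.

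Estimated counts were rounded to whole numbers, which changed none of them. Group and replicate number came from the sample titles. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM factors, filterByExpr by group and Benjamini-Hochberg adjustment at 0.05, on all 6 libraries with no covariate, which left 14667 genes. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Fold changes are libraries labelled KO over libraries labelled WT, and CPM values are scaled by TMM. The design, the alternatives and 43 gene lists were fixed before the data were examined. The lists were tested two-sided with camera at a preset inter-gene correlation of 0.01, adjusted over the 42 lists with tested members; the mitochondrially encoded list had none in the tables. Each list also has a count of members adjusted over the list alone. Switched genes had a mean count of at most 1 in one group and at least 10 counts in every library of the other, after thinning to 28136194 counts per library. Called genes were compared with tested genes per chromosome by Fisher's exact test, and the WT levels of higher and lower called genes by an exact permutation test.

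Dnmt3a was named first. The rule for other names took genes past the threshold with no overlap between the groups, a mean count of at least 50 and a symbol that is not a clone or predicted-gene name, up to 12 per direction, and then for each list up to 4 members past the threshold or, where none passed, the 2 with the highest mean CPM. Members that a list's count rests on could be named too. AI467606 falls outside the rule and was named because 5 genes were called, after its values were seen; Pecam1, Prox1, Dnmt3b and the antisense gene Dnmt3aos are outside the rule as well, and they, the switched genes and the genes named in the closing section from DESeq2 were likewise chosen after their values were seen.

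The alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, library size only, no filter, a mean count of at least 50, the replicate number as a block, robust dispersions, limma-voom with quality weights, limma on log2(TPM + 1) and log2(TPM + 0.1), a TPM filter, a test against a fold of 1.5, leaving out markers of other cell types, camera with an estimated correlation, fry, and leaving out each library in turn. Sex read from Xist and Y-linked genes as a covariate, an alveolar epithelial type 2 score as a covariate, both together, and male libraries only were added after the data were seen. A sign change was counted as a reversal where the gene passed the threshold in at least one of the fits compared.

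The test was tried on simulated data with the real library sizes and dispersions. edgeR recovered 30% of 100 genes changed 2-fold and 66% of 100 changed 4-fold, with 5 false calls over 14347 genes; DESeq2 recovered 56% and 77% with 48 false calls over 14667 genes. Library totals ran from 28136194 to 39999172 estimated counts, so that 3 counts, taken as the floor per library, correspond to 0.0796 to 0.102 CPM. Floors and counting intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Each library was taken as 1 sample. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 50.2 to 210), which does not show whether they came from separate animals.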

Results

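The study profiled RNA of lung endothelial cells, the cells that line blood vessels, sorted from mice labelled wild type or knockout for Dnmt3a, one of the enzymes that sets new DNA methylation. There were 3 libraries per label. The estimated counts summed to 31886755, 29482747 and 39999172 in WT replicates 1, 2 and 3 and to 28136194, 31402838 and 29221600 in KO replicates 1, 2 and 3, and 16647 to 17212 genes had a count in each library. Endothelial transcripts were abundant in every library: Pecam1, an endothelial adhesion molecule, lay between 1846 and 2461 CPM, and Cdh5, the endothelial cadherin, between 1989 and 2518 CPM. Xist and Y-linked genes showed a female replicate 1 and male replicates 2 and 3 under each label, so each label held at least 2 animals. Nothing in the labels says that all 3 libraries of a label came from separate animals, so p-values here measure the spread between these samples, which may be technical in part.

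The targeted gene was examined first. Dnmt3a (ENSMUSG00000020661, mm10 chromosome 12, 3806007 to 3914443, plus strand) had 1235, 1079 and 1198 estimated counts in WT replicates 1, 2 and 3 and 5090, 4878 and 4750 in KO replicates 1, 2 and 3. Its level was 35.3 ± 3.10 CPM in the libraries labelled WT and 165 ± 6.45 CPM in those labelled KO (mean ± SD, n = 3 each), a log2 fold change of 2.22 (SE 0.11, edgeR adjusted p = 0.00157). The gene thus ran against the labels, being higher in all 3 libraries labelled KO. For this reason the groups are called by their labels throughout, and every direction below is that of the libraries labelled KO relative to those labelled WT. A value summed over the whole gene need not fall when only some exons are deleted, and exon-level values were not analysed here. An antisense gene, Dnmt3aos, overlaps it on the same build (3859293 to 3862244, minus strand) but held only 10 to 26 counts per library.

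**Figure D1:**
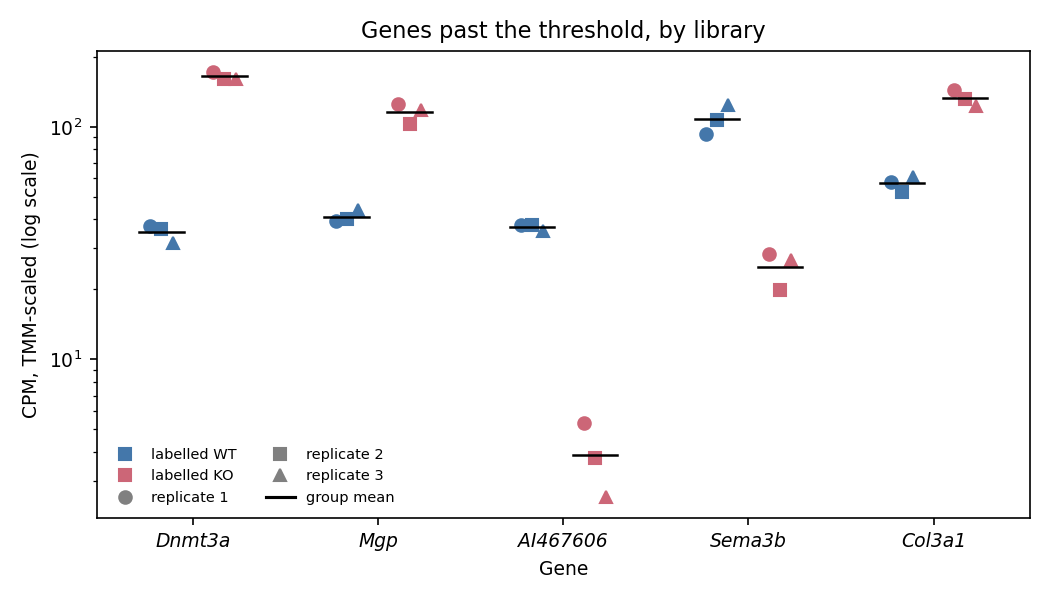
CPM on a log axis for the 5 genes past the threshold, with 1 point per library (colour for the label, shape for the replicate number) and a line at each group's mean. Dnmt3a, Mgp and Col3a1 lie higher in the libraries labelled KO and AI467606 and Sema3b lower, with no overlap between the groups.

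The comparison of the labels over all genes asks what differs in endothelial RNA between the genotypes. Besides Dnmt3a, 2 genes were higher in the libraries labelled KO. Mgp, which encodes matrix Gla protein, an inhibitor of calcification found in arterial walls (ENSMUSG00000030218, chromosome 6, 136872435 to 136875823), rose from 41.1 ± 2.38 to 116 ± 11.6 CPM, a log2 fold change of 1.49 (SE 0.12, adjusted p = 0.016). Col3a1, a fibrillar collagen chain (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706), rose from 57.2 ± 4.10 to 133 ± 10.4 CPM (log2 fold change 1.22, SE 0.11, adjusted p = 0.0223). Sema3b, a secreted semaphorin (ENSMUSG00000057969, chromosome 9, 107597674 to 107609229), fell from 108 ± 15.9 to 25.0 ± 4.49 CPM (log2 fold change -2.11, SE 0.18, adjusted p = 0.016). AI467606 (ENSMUSG00000045165, chromosome 7, 127091359 to 127093986), an uncharacterised protein-coding gene, fell from 37.1 ± 1.34 to 3.89 ± 1.39 CPM (log2 fold change -3.25, SE 0.27, adjusted p = 0.016). Markers of fibroblasts, a list that holds Col3a1, moved with the labels too: their summed level was 201 to 285 CPM in the libraries labelled WT and 357 to 527 CPM in those labelled KO. That sum includes Col3a1, so it is in part the called gene counted again.

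These 4 calls depended on which libraries were included. The call of Col3a1 ended without any of the 6 libraries (adjusted p = 0.0781 to 0.293). Mgp and Sema3b kept theirs only without KO replicate 2; without each other library the adjusted p was 0.0581 to 0.172 for Mgp and 0.0581 to 0.156 for Sema3b. AI467606 kept its call without KO replicate 1 or KO replicate 3 and lost it without WT replicate 1, 2 or 3 or KO replicate 2 (adjusted p = 0.0668 to 0.172). Log2 fold changes stayed at 1.42 to 1.54 for Mgp, 1.16 to 1.27 for Col3a1, -2.22 to -1.997 for Sema3b and -3.28 to -3.23 for AI467606 in the fits that lost the call. Over all alternatives the adjusted p reached from 1.35e-21 to 0.337 for Mgp, 2.04e-16 to 0.337 for Col3a1, 4.25e-23 to 0.207 for Sema3b and 6.43e-30 to 0.172 for AI467606, the lowest each time by DESeq2.

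In all, edgeR called 5 of 14667 genes, 3 higher and 2 lower, and 1855 genes had an unadjusted p under 0.05. Groups did not overlap for 20.3% of the tested genes, against 10% expected by chance with 3 libraries against 3. DESeq2, run as an alternative, called 406 genes, 213 higher and 193 lower, including all 5. In simulated data it made 48 false calls where edgeR made 5. Those data were drawn with dispersions that edgeR estimated, so they do not show how many of the 406 are false. Other splits of the 6 libraries gave DESeq2 3 to 209 calls. The count by edgeR fell to 1 without WT replicate 1 or without WT replicate 3, to 2 without KO replicate 3 and to 3 without KO replicate 1. It was 4 without WT replicate 2, of which 1 was among the 5, and 4 without KO replicate 2, of which 3 were. Dnmt3a passed in each of these 6 fits (adjusted p = 0.00991 to 0.0344). In fits chosen after the data were seen, edgeR called 2 genes with sex as a covariate, Dnmt3a and AI467606, and 0 in male libraries only (1572 at an unadjusted p under 0.05), where Dnmt3a had a log2 fold change of 2.22 (adjusted p = 0.168; range over the alternatives 5.19e-60 to 0.168).

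**Figure D2:**
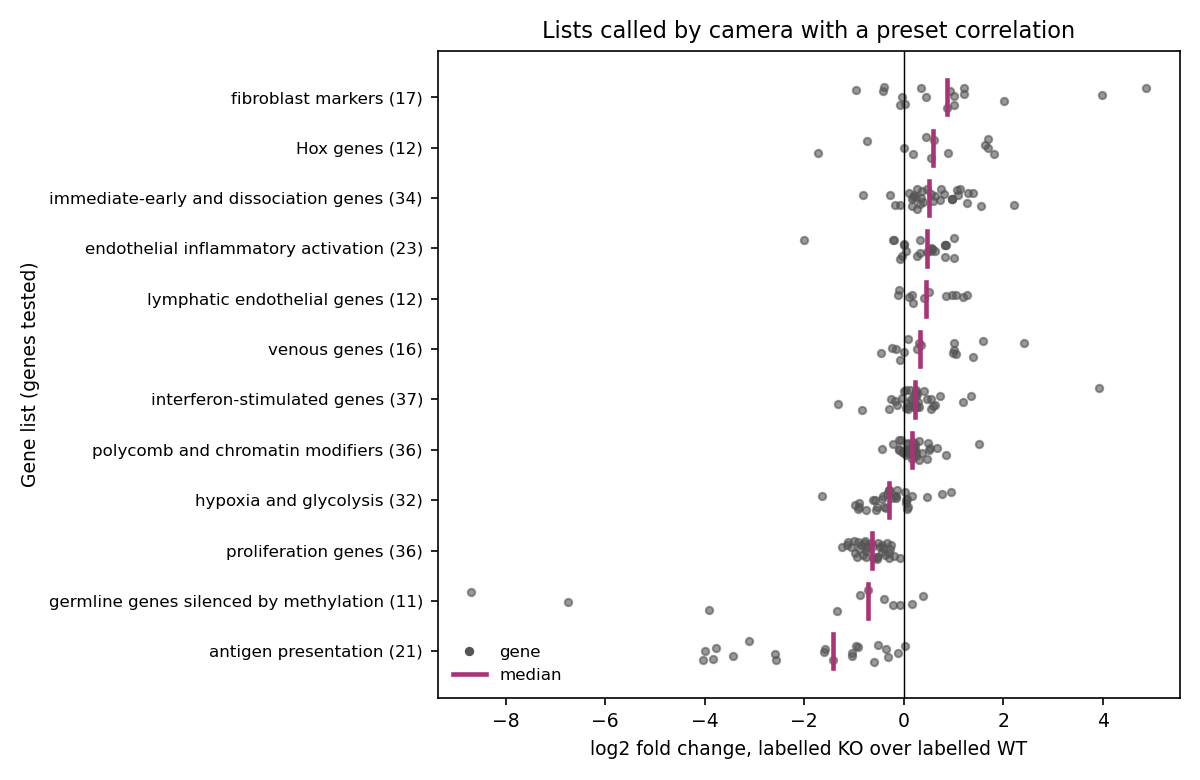
log2 fold change of the libraries labelled KO over those labelled WT for every tested member of the 12 lists called by camera with a preset correlation; points are genes and bars are medians, from -1.41 for antigen presentation to 0.88 for fibroblast markers. Values beyond about 6 on either side, as for Stk31 with no count in the libraries labelled KO, depend on the fit's prior and are not measured folds.

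Of 42 lists, 12 were called by camera with the preset correlation, 8 higher and 4 lower, and no list was called with an estimated correlation. Other splits of the 6 libraries into 3 against 3 called 3 to 14 lists, so a count of 12 is not particular to the labels. Antigen presentation genes were lower, with 20 of 21 measured members on the negative side and a median log2 fold change of -1.41 (camera adjusted p = 2.82e-08; adjusted p = 0.599 with an estimated correlation). No member passed over all genes tested, and 13 were lower adjusted over the list alone. Here and below, members are counted as passing by edgeR, whereas DESeq2 called 2 to 9 members over all genes in each of the 12 lists. H2-D1 and B2m, the heavy and light chains of MHC class I, were at 3768 and 1743 CPM in the libraries labelled WT and at 1846 and 844 CPM in those labelled KO (log2 fold change -1.03, SE 0.29, and -1.05, SE 0.33). Reads of H2-D1, H2-K1 and the H2-Q genes can be shared between these near-identical copies. Cd74, the MHC class II invariant chain, had 8129, 827 and 74617 counts in WT replicates 1, 2 and 3 and 2587, 662 and 842 in KO replicates 1, 2 and 3, so the groups overlapped. WT replicate 3 carried much of this list: without it the median was -0.70, with the list still called.

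Proliferation genes were lower as a list. All 36 measured members had a negative log2 fold change, with a median of -0.64 (camera adjusted p = 4.75e-10; adjusted p = 0.599 with an estimated correlation), and none passed over all genes or adjusted over the list alone. Stmn1, a tubulin-binding protein, and Top2a, the topoisomerase of dividing cells, had log2 fold changes of -0.27 (SE 0.13) and -0.79 (SE 0.36). The median was -0.36 without KO replicate 2 and -1.06 without KO replicate 1. Hypoxia and glycolysis genes were also lower (22 of 32 negative, median -0.30, camera adjusted p = 0.00453; adjusted p = 0.599 with an estimated correlation), with none passing over all genes or adjusted over the list alone; Pkm, a pyruvate kinase, was at 722 CPM in the libraries labelled WT and 431 CPM in those labelled KO. Without WT replicate 3 this median was -0.12. Epas1, the most abundant member, had a log2 fold change of 0.03 (SE 0.24).

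Germline genes that DNA methylation is known to silence were lower in the libraries labelled KO, with 9 of 11 measured members negative and a median of -0.72, the same with undetected genes set at their bound (camera adjusted p = 6.01e-05; adjusted p = 0.345 with an estimated correlation). No member passed over all genes, and 4 were lower adjusted over the list alone: Stk31, Syce1, Stag3 and Slc25a31. Restricted to genes with a mean count of at least 50, the list was not called (adjusted p = 0.39; range over the alternatives 3.92e-07 to 0.39). Stag3, a meiotic cohesin subunit, was at 3.23 CPM in the libraries labelled WT and 1.28 CPM in those labelled KO (log2 fold change -1.34, SE 0.35). The 2 most abundant germline members hardly moved. Tex14 was at 20.4 CPM in the libraries labelled WT and 17.6 CPM in those labelled KO (log2 fold change -0.21, SE 0.27). Ddx4 was at 3.40 and 3.23 CPM (log2 fold change -0.08, SE 0.36). Hox genes, the homeobox genes of body patterning, were higher (9 of 12 positive, median 0.58, camera adjusted p = 0.00221; adjusted p = 0.345 with an estimated correlation). Hoxb2, Hoxb3, Hoxb4 and Hoxb5 were the 4 higher members adjusted over the list alone, and none passed over all genes. Hoxb4 was at 3.33 CPM in the libraries labelled WT and 10.3 CPM in those labelled KO, and Hoxb5 at 7.14 and 23.2 CPM. The 2 most abundant Hox members, Hoxa5 and Hoxa3, had log2 fold changes of 0.18 (SE 0.25) and -0.0016 (SE 0.20). These 2 lists were also called by fry, which tests whether a list's members move on balance one way (adjusted p = 0.0112 for the germline list and 0.012 for the Hox list).

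Venous genes were higher (12 of 16 positive, median 0.33, camera adjusted p = 0.00539; adjusted p = 0.599 with an estimated correlation); Prss23, Slc6a2 and Vwf were the 3 higher members adjusted over the list alone, and none passed over all genes. Vwf, the clotting factor made by endothelium, was at 508 CPM in the libraries labelled WT and 1050 CPM in those labelled KO (log2 fold change 1.05, SE 0.21). Aplnr, the most abundant venous member, had a log2 fold change of -0.08 (SE 0.19). The list was no longer called without WT replicate 2 (adjusted p = 0.0517; range over the alternatives 0.000849 to 0.599), and its median was 0.58 without WT replicate 3. Lymphatic endothelial genes were higher (10 of 12 positive, median 0.45, camera adjusted p = 0.00453; adjusted p = 0.345 with an estimated correlation), with Lyve1, Sned1, Fgl2 and Pard6g higher adjusted over the list alone and none passing over all genes. Lyve1, a hyaluronan receptor, was at 374 and 899 CPM, while Prox1, the transcription factor of lymphatic identity, was at 1.11 and 2.29 CPM and did not pass. Without WT replicate 1 or 2 this median was 0.80 or 0.77. Flt4, the most abundant lymphatic member after Lyve1, had a log2 fold change of 0.16 (SE 0.17). Neither the arterial (16 of 27 positive, camera adjusted p = 0.524), general capillary (10 of 14 positive, 0.535), aerocyte (13 of 18 positive, 0.497) nor pan-endothelial list (14 of 33 positive, 0.535) was called. Among the arterial genes Mgp passed over all genes; adjusted over the list alone Mgp and Eln, the elastin gene, were higher and Gja4, an arterial connexin, was lower. Calcrl and Egfl7 had log2 fold changes of -0.20 (SE 0.24) and -0.18 (SE 0.19).

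Immediate-early and dissociation genes, which respond within minutes to stimulation or tissue handling, were higher (30 of 34 positive, median 0.51, camera adjusted p = 2.07e-06; adjusted p = 0.599 with an estimated correlation). None passed over all genes, and 7 were higher adjusted over the list alone: Junb, Egr1, Hspa1a, Hspa1b, Ier2, Ier5 and Jun. Egr1 was at 150 ± 31.6 CPM in the libraries labelled WT and 293 ± 66.8 CPM in those labelled KO, whereas the abundant member Nr4a1 had a log2 fold change of -0.81 (SE 0.34). Nr4a1 overlapped between the labels, at 542, 929 and 521 CPM in WT replicates 1, 2 and 3 and 354, 239 and 544 CPM in KO replicates 1, 2 and 3. Klf4, the most abundant member, had a log2 fold change of 0.26 (SE 0.22). Hspa1a and Hspa1b are near-identical, so that their reads can be split between them. Malat1, an abundant RNA retained in the nucleus, was also without overlap between the labels, at 9807, 10376 and 5861 CPM in WT replicates 1, 2 and 3 and at 12512, 20574 and 16343 CPM in KO replicates 1, 2 and 3 (log2 fold change 0.92, SE 0.26), and did not pass (edgeR adjusted p = 0.293). The nuclear retained RNAs (5 of 8 positive, camera adjusted p = 0.524) and the ribosomal protein genes (16 of 47 positive, camera adjusted p = 0.424) were not called as lists. Endothelial inflammatory activation genes (18 of 23 positive, median 0.48, camera adjusted p = 0.00605; adjusted p = 0.37 with an estimated correlation) and interferon-stimulated genes (30 of 37 positive, median 0.22, camera adjusted p = 0.00605; adjusted p = 0.599 with an estimated correlation) were higher as lists with no member passing either count. Without KO replicate 2 the first had a median of 0.29 and the second was not called (adjusted p = 0.197, range over the alternatives 0.000594 to 0.599, median 0.07). Nfkbia, the inhibitor of NF-kappaB, had a log2 fold change of 0.82 (SE 0.25). Ifitm3 and Lgals3bp, the 2 most abundant interferon-stimulated members, had log2 fold changes of 0.09 (SE 0.15) and -0.25 (SE 0.19). Polycomb and chromatin modifiers were higher by a median of 0.18 (29 of 36 positive, camera adjusted p = 0.00851; adjusted p = 0.599 with an estimated correlation) with no member passing either count; the call ended without WT replicate 3 (adjusted p = 0.133, median 0.08) and without KO replicate 1 (adjusted p = 0.055, median 0.10), with a range of 0.00324 to 0.599 over the alternatives. Crebbp and Kmt2d, the 2 most abundant of these, had log2 fold changes of -0.03 (SE 0.12) and 0.20 (SE 0.11).

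**Figure D3:**
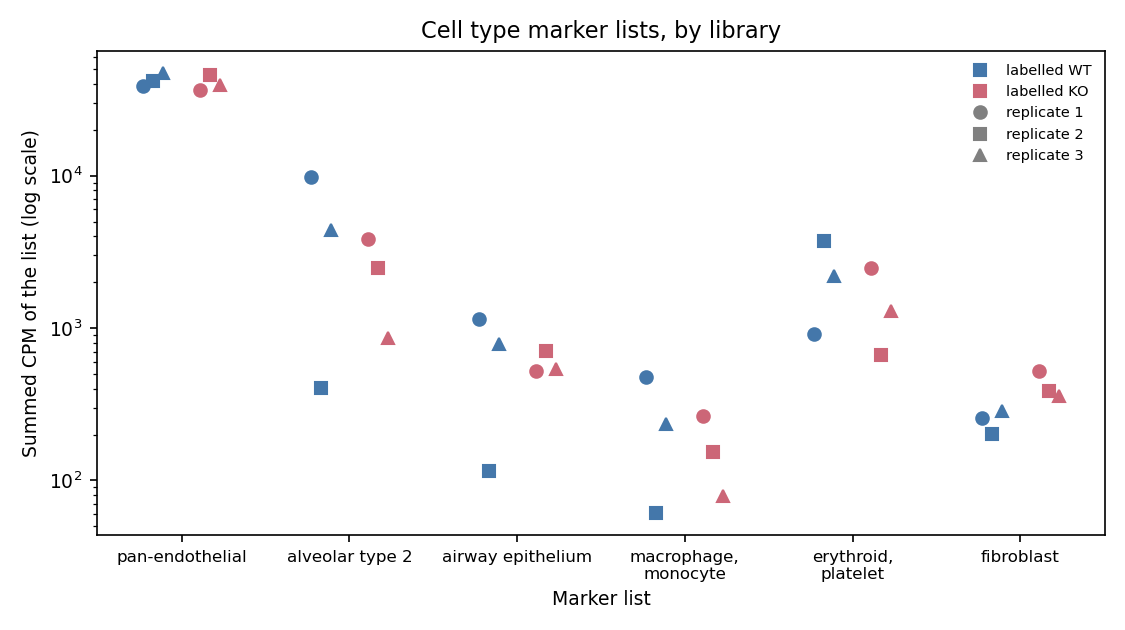
Summed CPM of 6 marker lists on a log axis, with 1 point per library (colour for the label, shape for the replicate number). Alveolar type 2 markers range from 407 to 9852 CPM within the libraries labelled WT, while fibroblast markers, Col3a1 included, lie between 201 and 285 CPM in those labelled WT and between 357 and 527 CPM in those labelled KO.

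Markers of other cells were measured beside these lists. Fibroblast markers were higher in the libraries labelled KO (12 of 17 positive, median 0.88, camera adjusted p = 0.00158; adjusted p = 0.599 with an estimated correlation), with a median of 0.46 without WT replicate 1 and 0.56 without KO replicate 1. Restricted to genes with a mean count of at least 50 it was not called (adjusted p = 0.0683; range over the alternatives 3.64e-05 to 0.599). Col3a1 passed over all genes, and Col3a1, Dcn, Inmt, Col1a1 and Npnt were the 5 higher members adjusted over the list alone. Dcn, the proteoglycan decorin, had 4, 4 and 8 counts in WT replicates 1, 2 and 3 and 78, 78 and 73 in KO replicates 1, 2 and 3. Alveolar epithelial type 2 markers varied widely within each label: Sftpc, the surfactant protein C gene, was at 7762, 173 and 3310 CPM in WT replicates 1, 2 and 3 and at 2927, 1837 and 548 CPM in KO replicates 1, 2 and 3, and the list was not called (camera adjusted p = 0.535). Airway epithelial (adjusted p = 0.83), alveolar type 1 (0.571), macrophage (0.535), erythroid and platelet (0.299), pericyte and smooth muscle (0.696), mesothelial (0.535), neutrophil (0.976), B cell (0.497) and T and NK cell lists (0.635) were not called. Medians and camera directions disagreed in sign for the airway list (median -0.33, camera higher). Sex was balanced between the labels.

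Imprinted genes, expressed from 1 parental copy, moved both ways. Of 30 measured members none passed over all genes and the list was not called (camera adjusted p = 0.228), while adjusted over the list alone 2 were higher (Sgce and Peg10) and 6 lower (Plagl1, Grb10, H19, Copg2, Ndn and Mest). Mest was at 511 CPM in the libraries labelled WT and 266 CPM in those labelled KO (log2 fold change -0.94, SE 0.27). H19, a noncoding RNA, had 3312, 4461 and 32116 counts in WT replicates 1, 2 and 3 and 910, 765 and 556 in KO replicates 1, 2 and 3. The DNA methylation machinery as a list was not called (camera adjusted p = 0.0759), and Dnmt3a was its only member past the threshold, over all genes and adjusted over the list alone; Dnmt3b had a log2 fold change of -0.69 (SE 0.22). Adjusted over the list alone, Igfbp3, Kcne3 and Vegfc were higher and Nid2 lower among 34 genes of VEGF signalling and sprouting (list adjusted p = 0.424), and Eln was higher and Nid2, Sparcl1 and Lamb1 lower among 34 genes of basement membrane and matrix (0.606, with a median of -0.04 and a mean of 0.07).

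The comparison of detected with nearly undetected genes asked which transcripts were at or close to 0 counts under 1 label, since methylation is often tied to silenced genes. After thinning, 4 genes had at least 10 counts in every library labelled KO and a mean of at most 1 in those labelled WT (Adamts2, Fam229b, Rps6kl1 and Vldlr), and 5 the reverse (Aass, Gdf11, Oacyl, Stk31 and Syce1). Adamts2, Fam229b, Vldlr and Stk31 had no count in the other group, and the other 5 had 1 or 2. Stk31, a kinase gene of male germ cells (chromosome 6, 49395604 to 49469501), had 44, 53 and 66 counts in WT replicates 1, 2 and 3 and none in the libraries labelled KO, at least 16.2-fold lower against the floor of 3 counts per library. Syce1, a component of the synaptonemal complex of meiosis (chromosome 7, 140777229 to 140787852), had 36, 57 and 70 counts against 1, 0 and 0, a ratio of 146 (95% counting interval 25.8 to 5784). Vldlr, a lipoprotein receptor (chromosome 19, 27216484 to 27254231), had no count in the libraries labelled WT and 49, 20 and 64 in KO replicates 1, 2 and 3, at least 16.5-fold higher. Of the 9, 8 were tested by edgeR (Oacyl was not, having been filtered out) and none of these passed its threshold (Stk31 and Syce1 adjusted p = 0.136). At a minimum of 20 counts 2 of the 9 remained, both higher in the libraries labelled WT. Leaving out a library raised the count to between 19 (KO replicate 2) and 36 (WT replicate 2), with 20, 20, 29 and 21 without WT replicate 1, WT replicate 3, KO replicate 1 and KO replicate 3. The balance of directions moved too: without WT replicate 2, 6 were higher and 30 lower in the libraries labelled KO, and without KO replicate 1, 9 and 20; the 4 other fits had 9 to 11 in each direction.

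No concentration of called genes on a chromosome was found, though with only 5 genes the test could show little short of an extreme one. The 5 genes lay on chromosomes 1, 6, 7, 9 and 12, and no chromosome passed Fisher's exact test (0 of 21, lowest unadjusted two-sided p = 0.161). That lowest value was for chromosome 12, which holds Dnmt3a itself. Among the 493 genes with an unadjusted p under 0.01 no chromosome passed either, with 2 at an unadjusted p under 0.05 and a lowest adjusted p of 0.203 for chromosome 11. Within 10 Mb of Dnmt3a none of the 40 other tested genes was called. The median WT level of the 3 higher genes was 1.46 log2 TPM units below that of the 2 lower ones (difference -1.46, two-sided exact permutation p = 0.5, smallest possible 0.1); in CPM the difference was -0.62.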

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

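Fits with sex, the epithelial score or both as covariates, and male libraries only, were chosen after seeing the data. No gene or list past the threshold, in the reported fit or in the alternative, changed direction. All 5 called genes were shared with DESeq2, the 3 other scalings and the 3 other filters on low values. The count of called genes was 5 to 7 under the other scalings, filters, robust dispersions, voom, log2(TPM + 1) and the epithelial score, 4 with markers of other cell types left out (Col3a1 among them), but 406 by DESeq2 (213 higher, 193 lower), 9 on log2(TPM + 0.1), 3 against a fold of 1.5 (a stricter hypothesis), 2 with sex as a covariate, 2 with sex and the epithelial score, and 0 by edgeR in male libraries only (1572 at an unadjusted p under 0.05); it was 1 to 4 without 1 library. The fits without 1 library and of male libraries use fewer samples; for DESeq2, the TPM pseudocount and the sex covariate, alone or with the score, the cause was not tested. Dnmt3a had a log2 fold change of 2.15 to 2.32 throughout and missed the threshold in male libraries only (2.22, adjusted p = 0.168) and with the replicate block (2.23, adjusted p = 0.0679; range over the alternatives 5.19e-60 to 0.168). Mgp, Col3a1 and Sema3b also missed it with sex as a covariate (adjusted p = 0.0591 each). Libraries with one replicate number share the sex read from the data, and whether they share a litter or day is not given in the sources used here. Same-number deviations correlated at 0.28, -0.05 and -0.18, and not every library correlated best with its own number, so the numbers were not taken as pairs. With the replicate number as a block edgeR called 0 genes (1472 at an unadjusted p under 0.05) and 12 lists; the cause was not tested. An estimated correlation left 0 lists (4 at an unadjusted p under 0.05) and fry 2, while leave-one-out gave 12 to 14, of which 11 or 12 were among the 12, and a mean count of at least 50 gave 10; an estimated correlation also lowers camera's degrees of freedom to the residual ones and fry tests another hypothesis, and which of these matters was not tested. Switched genes numbered 2 at a minimum of 20 counts and 19 to 36 without 1 library, both by construction of the criterion. Depth sets the floor under which a gene's absence cannot be shown: 3 counts correspond to 0.0796 to 0.102 CPM.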

Other observations

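Of the tests in this part, those of library size or composition and of the effective length of Dnmt3a, of epithelial RNA as the source of the called genes, and of the glucocorticoid list were chosen only after the result was seen. Beyond the genes of the report, DESeq2 called several transcripts that edgeR did not, named here after their values were seen. All those named in this paragraph were lower in the libraries labelled KO, whereas DESeq2 called 213 genes higher and 193 lower. Trf, the iron carrier transferrin, was at 311 ± 61.6 CPM in the libraries labelled WT and 109 ± 28.7 CPM in those labelled KO (DESeq2 adjusted p = 6.93e-08, edgeR adjusted p = 0.191). Dusp6, a phosphatase that restrains ERK signalling, was at 1179 ± 369 and 443 ± 72.8 CPM (DESeq2 adjusted p = 1.1e-06, edgeR adjusted p = 0.216), and Clu, the chaperone clusterin, at 292 ± 56.2 and 133 ± 31.4 CPM (DESeq2 adjusted p = 4.23e-05, edgeR adjusted p = 0.23). For these 3 genes DESeq2 gave the lowest adjusted p of the alternatives and the fit without WT replicate 3 the highest (0.508, 0.482 and 0.607). Pcdhga11 and Pcdhgb7 are variable members of the gamma-protocadherin cluster whose last exons are shared with the rest of the cluster. They had log2 fold changes of -1.34 (SE 0.16) and -0.81 (SE 0.12). Their adjusted p-values were 0.0921 and 0.191 by edgeR and 2.96e-09 and 2.28e-05 by DESeq2.

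Dnmt3a and part of the germline genes ran against the labels, and library size or composition is argued against for Dnmt3a: in counts with no scaling its log2 ratio was 2.07, while the median of all tested genes was -0.15 (SD over genes 0.57). Reversed group labels remain open and are not established: they would give less Dnmt3a and more Stk31 and Syce1 in true knockouts. A further list of 18 tested germline genes gave no call either way (camera p = 0.939, direction lower, with a median of 0.05; p = 0.942 with an estimated correlation). A deleted allele whose transcript is kept at a higher level may also give these values; the effective length of Dnmt3a was shorter by -0.0407 log2 units in the libraries labelled KO, at the edge of the central 95% of 6963 genes (-0.0406 to 0.0578), with a gap of only 0.000606 between the groups against a range of 0.0459 within one. Requiring that gap to exceed the range was decided after the value was seen (by non-overlap alone the prediction was met), reversed labels would allow a difference in isoforms too, and the 2 explanations cannot be told apart with gene-level values.

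Alveolar epithelial RNA differed widely between libraries of one label, although the sort was for endothelial cells: summed type 2 markers ranged from 407 to 9852 CPM in the libraries labelled WT, and pan-endothelial genes from 38501 to 47328 CPM. The 15 type 2 markers other than Sftpc had a median SD of 1.87 log2 units over the 6 libraries and 0.369 relative to Sftpc. Type 2 markers thus varied together, as cells or RNA of one epithelial source in varying amounts would give. Airway markers did not keep a fixed ratio to them. Summed airway markers were at 1142 CPM in WT replicate 1, where type 2 markers were at 9852 CPM. In KO replicate 3 the sums were 539 and 866 CPM. Sftpc, the most abundant, had 255091 counts in WT replicate 1 and 5097 in WT replicate 2, and no gene of the list is in another of the 43 lists. With the epithelial score as a covariate, 5 of 5 called genes kept their log2 fold change to at least 0.5 of its size. Sftpc moved from -1.08 to 0.21, but it is itself part of the score, so this shift was built in. This fit could decide little about their source, because the score overlapped between the labels. It was 6.69, 2.28 and 5.70 log2 CPM in WT replicates 1, 2 and 3 and 5.47, 4.68 and 3.57 in KO replicates 1, 2 and 3. Type 2 RNA thus did not separate the labels. The 5 called genes did, but they had been selected for a difference between the labels. No such fit was run with fibroblast markers. No biological explanation of the spread in epithelial RNA was tested.

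Per1, a clock gene also induced by glucocorticoids, had 870, 1228 and 917 counts in WT replicates 1, 2 and 3 and 3472, 5048 and 4910 in KO replicates 1, 2 and 3 (log2 fold change 2.29, SE 0.24, edgeR adjusted p = 0.057). Another time of day at collection cannot be told apart from other explanations: without Per1, evening-phase and morning-phase clock genes were both higher, by medians of 0.56 and 0.59, a difference of -0.0307 (camera p = 0.000856 and 0.00211; p = 0.0788 and 0.035 with an estimated correlation). That explanation would put morning-phase genes lower, but the difference changed sign between the fits without 1 library (-0.21 to 0.09), the morning-phase median was 0.37 without KO replicate 2, and none of its 5 genes passed adjusted over the list alone (lowest adjusted p = 0.0744). Glucocorticoid exposure or stress may contribute: without Per1, Klf9, Gadd45g and Slc10a6, whose values had been seen (the last 2 left out only after a first test with them), 13 of 15 response genes were positive with a median of 0.82 (camera p = 0.000767; p = 0.127 with an estimated correlation), and without KO replicate 2 the median was 0.50 (camera p = 0.00437). The 2 negative members were Sgk1 (log2 fold change -0.93, SE 0.35) and Mt1 (-0.12, SE 0.92). Nfkbia, already named in the results, was kept among the 15 and its value is the median of 0.82. The list was thus not free of values seen before. The genotype stays open as an untested explanation, beside handling of the tissue.

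With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. edgeR's real count was 5 and the highest of the other splits 0 (1 split as large, the real one included), DESeq2's was 406 and 209 (1 split), the lists called were 12 and 14 (2 splits) and switched genes 9 and 23 (2 splits). The other splits called 7, 4, 14, 10, 11, 3, 11, 9 and 4 lists, so camera with the preset correlation called lists under every split. The split with 23 switched genes and 209 DESeq2 calls set WT replicates 1 and 3 and KO replicate 1 apart; these are the 3 libraries with the highest epithelial scores (6.69, 5.70 and 5.47 log2 CPM), so it points to a structure of the samples other than the labels.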
